A study of Mytilus galloprovincialis with 16 samples.

How the data were processed

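Gill RNA of the mussel Mytilus galloprovincialis was measured on 16 arrays of 1 colour (Cy3), and each array held a pool of 5 animals, per the series design text. The 16 pools fall into 4 groups of 4 by the labels' growth class, slow or fast, and by the diet in the laboratory, BP or AP. All animals were labelled submerged. The labels do not spell out BP and AP, and they do not say how fast and slow growers were told apart. The pools of a group are separate pools and serve as its replicates. Their number limits the precision.

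The deposited scanner files give each spot's brightness as intensity on a linear scale. Per the file headers, Agilent Feature Extraction 10.7.3.1 subtracted the background and detrended each array to make the processed signal. A second deposited table, the authors' value table, holds values on the log2 scale, and how it was made is not stated. All 61392 entries of that table were matched to spots by feature number. Its columns were checked against the scanner files, and normexp with an offset of 50 followed by quantile normalization came within a median of 0.015 log2 of them and at most 0.12. The table is therefore read as log2 intensity, made equal in distribution between arrays and not centred per gene, and the median of every column was 7.18. It served as an alternative only.

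The array design holds 61392 spots, of which 59539 are not controls and carry 59314 different probes of 60 bases for 25753 target names. Of the names, 25719 are contig numbers with no gene attached. The other 34 hold a gene word or symbol, of which 12 end in F, 12 end in M and 10 are other names. The endings F and M are read here as the female-type and male-type mitochondrial genomes that Mytilus mussels carry. In the gene table of the reference assembly xbMytGall1.hap1.1, 0 of the target names were found, so contigs are given by the number in the files and no gene was assigned to them.

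The processed signal was taken to log2, and each array's 75th percentile over the spots that are not controls was subtracted. Levels are therefore log2 values relative to that percentile. Spots marked as non-uniform or population outliers were left out, 6 to 55 per array, and repeated spots of a probe were averaged. A probe was tested if it was well above background, by the scanner's own call, on at least 3 of the 4 arrays of at least 1 group. This left 40426 probes for 20876 names. The probe was the unit of testing, since most names have several probes.

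Group means were fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). P-values were two-sided and were adjusted by Benjamini-Hochberg within each comparison. A probe counts as called at an adjusted p under 0.05. The comparisons were fast minus slow over both diets, fast minus slow in each diet, BP minus AP over both growth classes, BP minus AP in each class, and the difference of the growth differences. Contigs with a called probe were joined into sequence groups with igraph 2.1.4. They were joined where any of their probes, called or not, shared a stretch of 25 bases on either strand. Where a probe was well above background on no array of a group, a bound is given as "at least N-fold": that group was set, per array, to the higher of its own value and the lowest signal among probes well above background. A group with any array well above background kept its own values. Where the dim side holds such a group with dim arrays, the fold is not a strict lower bound.

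Of 29 gene lists fixed before the data were examined, 1 could be tested, oxidative phosphorylation, with 15 measured names and 1 probe per name. Another 2 lists had 1 to 4 measured members and 26 had none, because the contigs carry no names. The list was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with limma's fry. The rule for the names given in the text was also fixed before the data were examined: the named probes past the threshold with the largest changes, or, where fewer than 10 passed, the 10 named probes with the smallest p as values that did not pass. Of the probes without a gene name, the text gives the 2 contigs that rose most and the 2 that fell most.

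The arrays lie on 3 slides of 4, 6 and 6 arrays, and each slide holds all 4 groups. Fast and slow pools of each diet are equal in number on every slide. Diet is not even: slide 2 holds more BP than AP pools, and slide 3 more AP than BP pools. Slide was tested as a block and within each slide. The alternatives covered the background correction, normalization between arrays, the filter, outlier spots, the authors' value table, slide, pool number, variance model, array weights, thresholds and number of probes per name. In addition, each pool was left out in turn, which is reported apart from the alternatives.

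The fit was tested on simulated data with known changes of 4 sizes, each added to 50 of the 40426 probes. For the growth difference over both diets, it recovered 13 of 50 probes changed by 0.5 log2, 33 of 50 changed by 1 log2, 45 of 50 changed by 2 log2 and 50 of 50 changed by 3 log2, with 4 false calls among 40226 unchanged probes. For BP alone it recovered 28 of 50 probes changed by 1 log2 and 32 of 50 changed by 2 log2. For AP alone it recovered 24 of 50 and 34 of 50. The simulated noise was independent between probes and held no slide difference and no background floor. These counts therefore need not hold for the real arrays.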

Results

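Gene expression was measured in the gills of fast-growing and slow-growing mussels that were reared on either of the diets BP and AP. Each of the 4 groups holds 4 pools of 5 animals. On the 16 arrays the 75th percentile of the processed signal lay between 8.50 and 9.03 log2, and between 50.3% and 72.9% of the spots were well above background. The share was lowest on slide 1, at 50.3% to 58.3%, against 62.4% to 72.9% on slides 2 and 3. Any pair of arrays correlated at 0.927 to 0.959 across probes, and 0 to 2 spots per array were saturated.

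The growth comparison asked which gill transcripts differed between fast and slow growers, as the series title puts it. Over both diets, fast growers had higher levels of 93 contigs and lower levels of 98 contigs. On the processed signal the median fall among the 128 lower probes was -1.86 log2, and the median rise among the 122 higher probes was 0.70 log2. The gap depended on the background correction, since the same probes had medians of -0.97 and 0.63 log2 with normexp and -0.98 and 0.61 log2 in the authors' value table. Among the called probes well above background on all 16 arrays, 47 lower and 112 higher, the medians were -1.54 and 0.68 log2 on the processed signal and -1.29 and 0.59 log2 with normexp. On the processed signal a change of at least 1 log2 was reached by 114 of the lower probes and by 29 of the higher ones.

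The contigs that rose most were mgal_est_8327 and mgal_nuc_12275, which belong to the same sequence group. In mgal_est_8327 the level was -4.04 ± 1.44 (SD, n = 4) in BP slow, -1.37 ± 0.49 in BP fast, -3.24 ± 0.52 in AP slow and -1.20 ± 0.70 in AP fast. This is a rise of 2.35 log2 (SE 0.40, limma adjusted p = 0.0179), or 5.11-fold, and all 8 fast pools lay above all 8 slow pools. The level of mgal_nuc_12275 rose by 2.09 log2 (SE 0.42, limma adjusted p = 0.0360), and 7 of the 8 fast pools lay above every slow pool. The probes with these values were dim, well above background in 1 of 4 pools of BP slow and in all pools of the other groups. Each of these contigs had a second tested probe that was also called and was brighter, well above background in every pool. It rose by 1.95 log2 in mgal_est_8327, from 2.45 in BP slow to 4.70 in BP fast and from 2.89 in AP slow to 4.54 in AP fast. In mgal_nuc_12275 it rose by 2.01 log2. The dim and the brighter probe of each contig come from 2 different probe sets of the array. Where pairs of these sets overlap they read opposite strands, so the probes may not measure the same transcript.

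The contigs that fell most were mgal_est_12480 and mgal_nuc_65. In mgal_nuc_65 the level was 0.98 ± 1.31 (SD, n = 4) in BP slow, -3.95 ± 1.81 in BP fast, -0.88 ± 1.73 in AP slow and -5.49 ± 1.14 in AP fast. It fell by 4.77 log2 (SE 0.69, limma adjusted p = 0.00856), and all 3 of its tested probes were called. It was well above background in 2 of 4 pools of BP fast and in 0 of 4 of AP fast. With only AP fast raised to the lowest signal well above background, the fall is 18.7-fold on the processed signal. The dim BP fast pools kept their own values, so this is not a strict lower bound. Over the alternatives the fall was between -5.55 and -2.54 log2, the smallest with the authors' value table, and the call was kept. The level of mgal_est_12480 fell by 5.00 log2 (SE 0.97, limma adjusted p = 0.0326), with wide spread among slow pools: 1.47 ± 3.31 (SD, n = 4) in BP slow and 2.09 ± 2.23 in AP slow. In BP fast it was well above background in 2 of 4 pools. Its second tested probe, from the other of the 2 probe sets named above, fell by 3.68 log2 and was not called (limma adjusted p = 0.194). In both contigs 7 of the 8 fast pools lay below every slow pool.

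**Figure D1:**
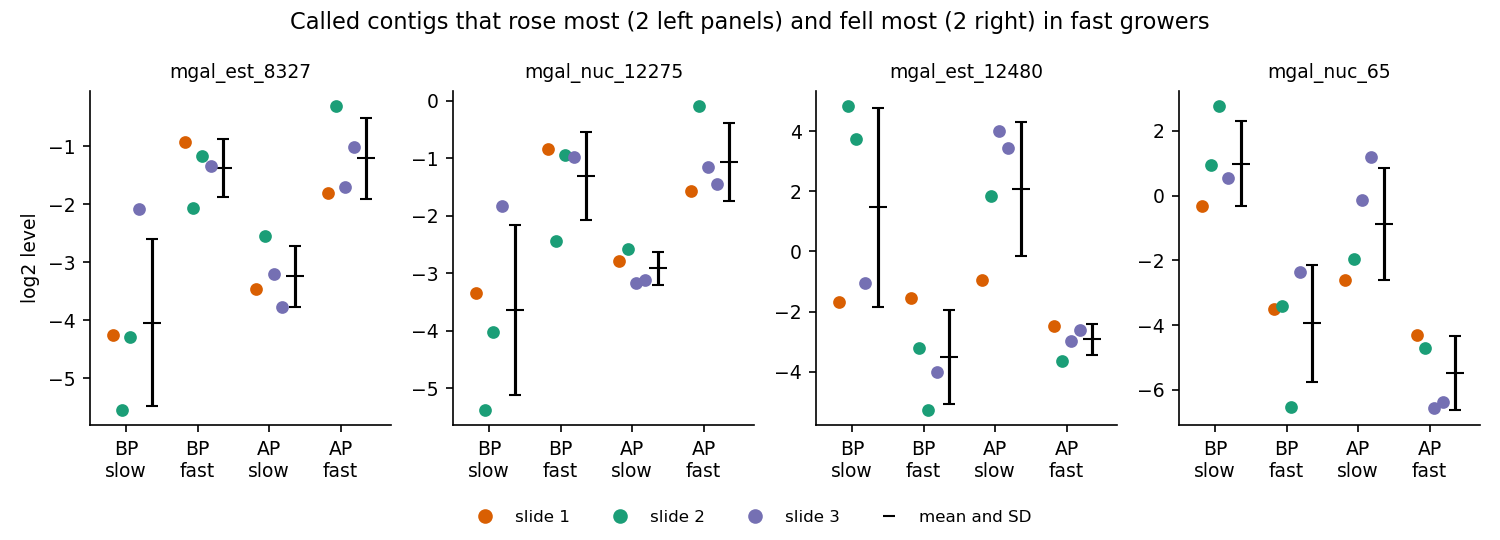
Level in each pool of the 2 called contigs that rose most and the 2 that fell most in fast growers (log2 relative to the array's 75th percentile), by diet and growth class. Each contig is shown by its called probe with the largest change. Points are pools coloured by slide, and bars are the mean and SD of 4 pools. In mgal_est_8327 all 8 fast pools lie above all 8 slow pools, and in the other 3 contigs 7 of the 8 fast pools lie beyond every slow pool.

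Called contigs whose probes share a stretch of 25 bases had the same sign in all but 1 group, in which 1 contig rose by 1.08 log2 and the other fell by 2.07 log2. The 191 contigs fell into 154 sequence groups, and the largest group held 11 contigs with 14 called probes, all lower in fast growers, with a median of -1.61 log2. The second group held 6 contigs with 11 called probes, all higher, with a median of 2.01 log2. Of the 159 contigs with more than 1 tested probe, 147 had the same sign in every probe. However, only 43 of the 159 had 2 or more probes called, and 26 had every tested probe called. The rises and falls also differed in how bright they were. Of the 122 higher probes, 112 were well above background on all 16 arrays, and of the 128 lower probes, 47 were. In 10 of the lower probes the signal was never well above background in a fast pool of either diet.

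The smallest adjusted p among the 250 called probes was 0.00856, and 4717 of the 40426 probes had an unadjusted p under 0.05. All 250 kept their sign within each of the 3 slides, with medians of 0.45, 0.92 and 0.62 log2 for the higher probes and -1.61, -1.85 and -1.70 log2 for the lower probes. The 250 were chosen from these same arrays, so this is no independent support. With slide as a block 339 probes were called, 209 higher and 130 lower, and 228 of the 250 were among them. Without the 4 arrays of slide 1 the count was 83, of which 53 were among the 250, and leaving out a single pool moved it between 97 and 333. The call of mgal_est_12480 ended with normexp (adjusted p = 0.0690) and with the authors' value table (0.0700), in a range of 0.0131 to 0.0700 over its alternatives. Those of mgal_est_8327 (adjusted p = 0.103, range 0.00804 to 0.103) and mgal_nuc_12275 (0.132, range 0.0334 to 0.132) ended without slide 1, and the latter also without an intensity trend (0.0505). With each pool left out in turn, mgal_nuc_12275 lost its call in 12 of the 16 fits and mgal_est_12480 in 11, while mgal_est_8327 and mgal_nuc_65 kept theirs in all 16.

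Of the 60 tested probes with a gene name, 0 were called by limma between fast and slow growers, and 0 passed when adjusted over the named probes alone, although 49 were higher in fast growers. Of the 10 with the smallest p, which were followed under the alternatives, some then gained a call, ND3_mgal_F with slide as a block (adjusted p = 0.0450, range 0.0450 to 0.692 over its alternatives) and 2 probes of ND4L_mgal_F with array weights (0.0426 and 0.0391, ranges 0.0426 to 0.223 and 0.0391 to 0.237). The 10 smallest p-values belonged to mitochondrial names. Of these, 9 probes were of the female type, all higher in fast growers by 0.17 to 0.33 log2. They target ND4L_mgal_F, ND3_mgal_F and ND4_mgal_F, which are subunits of NADH dehydrogenase, COX1_mgal_F and COX3_mgal_F, which are subunits of cytochrome c oxidase, and ATP6_mgal_F, a subunit of ATP synthase. The ND4L_mgal_F probe with the smallest p differed by 0.33 log2 (SE 0.08, limma adjusted p = 0.0927). The remaining probe, of COI_mgal_M, differed by -2.51 log2 (SE 0.84, adjusted p = 0.213), and another probe of the same name differed by -0.67 log2 (adjusted p = 0.565). The names of the cytoskeleton and of translation were close to 0. They were actin (0.12 log2), alpha-tubulin (0.09), elongation factor 1 alpha (0.06), ribosomal protein P0 (0.03), a ribosomal name (0.01) and a 40S ribosomal name (-0.01). Their adjusted p-values were 0.630 or higher, and 5 of the 6 were above 0 with the 75th percentile but 3 with quantile normalization and with the authors' value table. Alpha-tubulin was the only measured member of the cilia list, and an RNA-binding name that of the gonad list (-0.09 log2, limma adjusted p = 0.657).

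The oxidative phosphorylation list was higher in fast growers at the preset correlation of limma's camera (p = 0.000653), with 13 of 15 members above 0, 0 members past the threshold and 0 past it when adjusted over the list alone. All its members are female-type or male-type mitochondrial names, so it overlaps the female-type list below and holds no subunit encoded in the nucleus. Of the 12 female-type and 9 male-type names tested, only these 15 matched the list by name. COI_mgal_M, at -2.51 log2, was not among them, since the lowest member was at -0.63 log2. The list's median was 0.12 log2 and its mean 0.08 log2. With an estimated correlation the call was lost (p = 0.0531), and it was lost with quantile normalization (p = 0.657) and with the authors' value table (p = 0.506). Limma's fry, which allows for the correlation among the probes, gave p = 0.0141 for a shift in a common direction and p = 0.0597 for a change in either direction. The list's mean difference was -0.08 log2 within slide 1, 0.18 within slide 2 and 0.06 within slide 3.

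The 12 female-type names, taken as a list only after the data were seen, had a mean level of 8.46 ± 0.14 (SD, n = 4) in BP slow, 8.63 ± 0.07 in BP fast, 8.52 ± 0.04 in AP slow and 8.62 ± 0.12 in AP fast. Above 0 were 12 of the 12 names with the 75th percentile and with normexp, 11 with the median of detected probes, 8 with quantile normalization and 7 with the authors' value table. Camera gave p = 4.06e-06 at the preset correlation, and this call was lost with an estimated correlation (p = 0.0748), with quantile normalization (p = 0.50) and with the authors' value table (p = 0.407). Within slides the mean difference over both diets was 0.07, 0.19 and 0.18 log2. By single diet it was -0.06, 0.21 and 0.34 log2 in BP and 0.20, 0.17 and 0.02 log2 in AP. The 9 male-type names tested went both ways, with a median of 0.00 log2 and a mean of -0.42 log2 (camera p = 0.516 at the preset correlation).

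**Figure D2:**
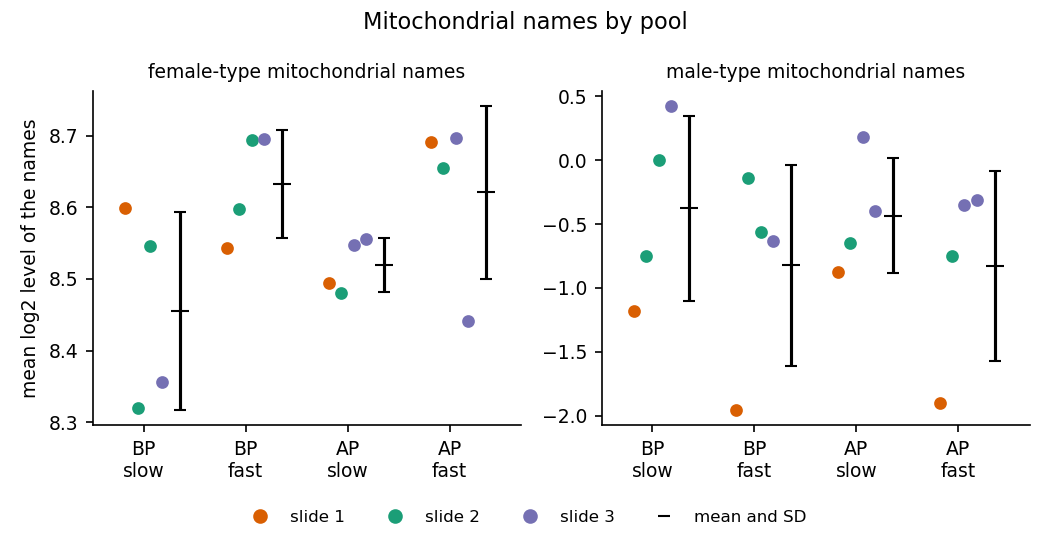
Mean log2 level of the 12 female-type and 9 male-type mitochondrial names in each pool, by diet and growth class. Points are pools coloured by slide, and bars are the mean and SD of 4 pools. The female-type mean was 8.46 in BP slow and 8.63 in BP fast, with every name above 0 in fast minus slow under the 75th percentile scaling but 8 of 12 under quantile normalization and 7 of 12 in the authors' value table.

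Within each diet alone, limma called no difference between fast and slow growers. Of the contigs named for the mean of both diets, mgal_est_8327 and mgal_nuc_65 are given here as values that did not pass. In BP, mgal_est_8327 was at 2.67 log2 (SE 0.57, limma adjusted p = 0.159) and mgal_nuc_65 by -4.93 log2 (SE 0.97, adjusted p = 0.124). In AP mgal_est_8327 was at 2.04 log2 (SE 0.57, adjusted p = 0.397). In mgal_nuc_65 no AP fast pool was well above background, and the fall there is at least 11.4-fold (adjusted p = 0.253). Limma, the only tool run on single probes, called 0 probes in BP, where 3456 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0904. It called 0 probes in AP, where 2861 had an unadjusted p under 0.05 and the smallest adjusted p was 0.146. In BP the count became 8 with normexp and 20 without BP slow pool 4, and in AP it became 7 without AP slow pool 3 or AP fast pool 3. Of the named probes, the smallest p in BP belonged to ND4_mgal_F (0.44 log2, adjusted p = 0.234) and in AP to COI_mgal_M (-2.85 log2, adjusted p = 0.648), whose other tested probe was at 0.70 log2 (adjusted p = 0.882). The other 9 named probes with the smallest p had adjusted p-values up to 0.471 in BP and up to 0.839 in AP. The oxidative phosphorylation list gave camera p = 0.00140 in BP and 0.0187 in AP at the preset correlation, and p = 0.0674 and 0.165 with an estimated correlation. Camera at the preset correlation gave p = 0.506 in BP and 0.987 in AP with quantile normalization, and p = 0.546 and 0.670 with the authors' value table, so neither call was kept.

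The growth difference was then compared between the diets, which share no pools. Across the 40426 probes the fast minus slow differences in BP and AP correlated at 0.279, where probes are not independent replicates. At an unadjusted p under 0.05 in both diets, 442 probes were higher in fast growers in both, against 67.2 that independent lists would share, and 342 were lower in both, against 55.4. Opposite directions were seen in 30 probes, against 122.0. Of the 250 probes with the smallest p in BP, 230 (92.0%) had the same sign in AP, and of the 250 with the smallest p in AP, 213 (85.2%) had the same sign in BP.

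**Figure D3:**
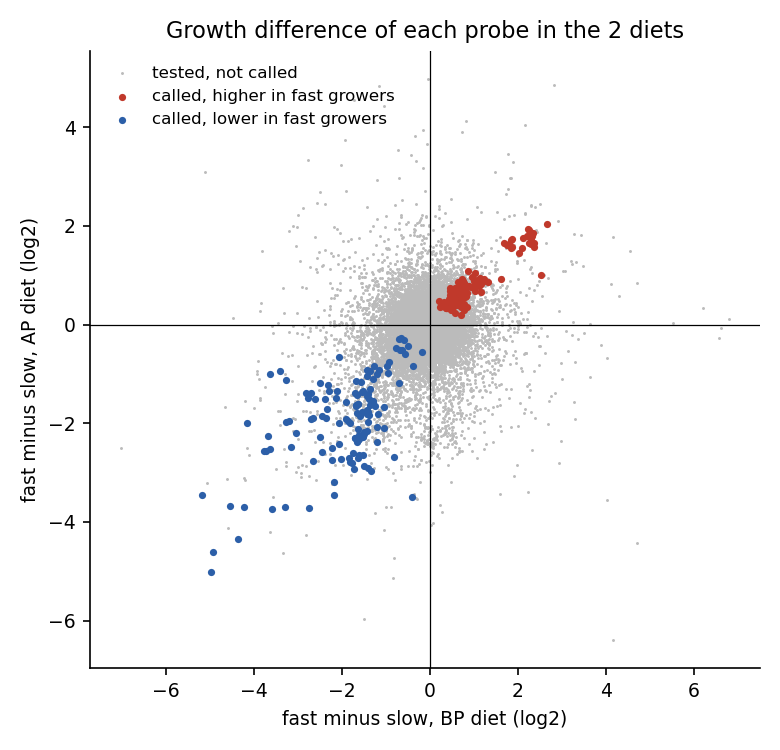
Fast minus slow difference of each tested probe (log2) in BP on the horizontal axis and in AP on the vertical axis. Grey points are probes that were not called, red points the 122 called higher and blue points the 128 called lower over both diets. Over all 40426 probes the correlation is 0.279.

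The test of whether the growth difference itself differed between diets called 0 probes with limma, where 1258 had an unadjusted p under 0.05 and the smallest adjusted p was 1.00. The growth difference in BP minus that in AP was 0.63 log2 (SE 0.80) for mgal_est_8327, 0.49 (SE 0.83) for mgal_nuc_12275 and 0.03 (SE 1.94) for mgal_est_12480. None is given for mgal_nuc_65, which was well above background in 0 of 4 pools of AP fast. Without AP fast pool 3, 4 probes were called, and without BP fast pool 1, 1 probe was called. The smallest adjusted p of a named probe was 1.00, and the oxidative phosphorylation list gave camera p = 0.358 at the preset correlation.

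The diet comparison asked which transcripts differed between mussels on BP and on AP. Few were called. Over both growth classes limma called 9 probes of 7 contigs, 4 higher and 5 lower in BP, and 4024 probes had an unadjusted p under 0.05. The contig that rose most in BP was mgal_nuc_20767, at 0.01 ± 0.37 (SD, n = 4) in BP slow, -0.13 ± 1.07 in BP fast, -4.21 ± 2.40 in AP slow and -5.18 ± 1.54 in AP fast. This is a difference of 4.64 log2 (SE 0.69, limma adjusted p = 0.0491). In AP slow and in AP fast 1 of 4 pools was well above background. The second tested probe of mgal_nuc_20767, from the probe set that may read the opposite strand, differed by 1.01 log2 and was not called (limma adjusted p = 0.277). With normexp the difference of mgal_nuc_20767 was 2.43 log2 (adjusted p = 0.0631), and over the alternatives it was between 2.41 and 4.96 log2 (adjusted p of 0.0232 to 0.118). With a pool left out it was between 4.36 and 5.23 log2, the highest without AP slow pool 4, and the call was lost in 14 of 16 fits. The contig mcal_est_11337 rose by 0.76 log2 in BP (SE 0.12, limma adjusted p = 0.0491), with all 8 BP pools above all 8 AP pools, and 2 of its 3 tested probes were called.

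Lower in BP were mgal_nuc_32645 and medu_nuc_229. In mgal_nuc_32645 the level was -2.86 ± 0.28 (SD, n = 4) in BP slow, -3.29 ± 0.44 in BP fast, -1.18 ± 0.48 in AP slow and -1.06 ± 0.44 in AP fast. It fell by 1.96 log2 (SE 0.20, limma adjusted p = 0.00325) and was well above background in 3 of 4 pools of each BP group. In medu_nuc_229 the level fell by 1.66 log2 (SE 0.21, limma adjusted p = 0.0131). It was well above background in 1 of 4 pools of BP slow, 0 of 4 of BP fast and 3 of 4 of AP fast. Its second tested probe was not called (limma adjusted p = 0.270). With only BP fast raised to the lowest signal well above background, the called probe's fall is 2.21-fold on the processed signal. The dim BP slow pools kept their own values, so this is not a strict lower bound. The size depended on the background correction, since the difference was -0.38 log2 with normexp and was not called (adjusted p = 0.177), in a range of -1.87 to -0.38 log2 over the alternatives (adjusted p of 0.00235 to 0.177). In both contigs all 8 BP pools lay below all 8 AP pools.

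**Figure D4:**
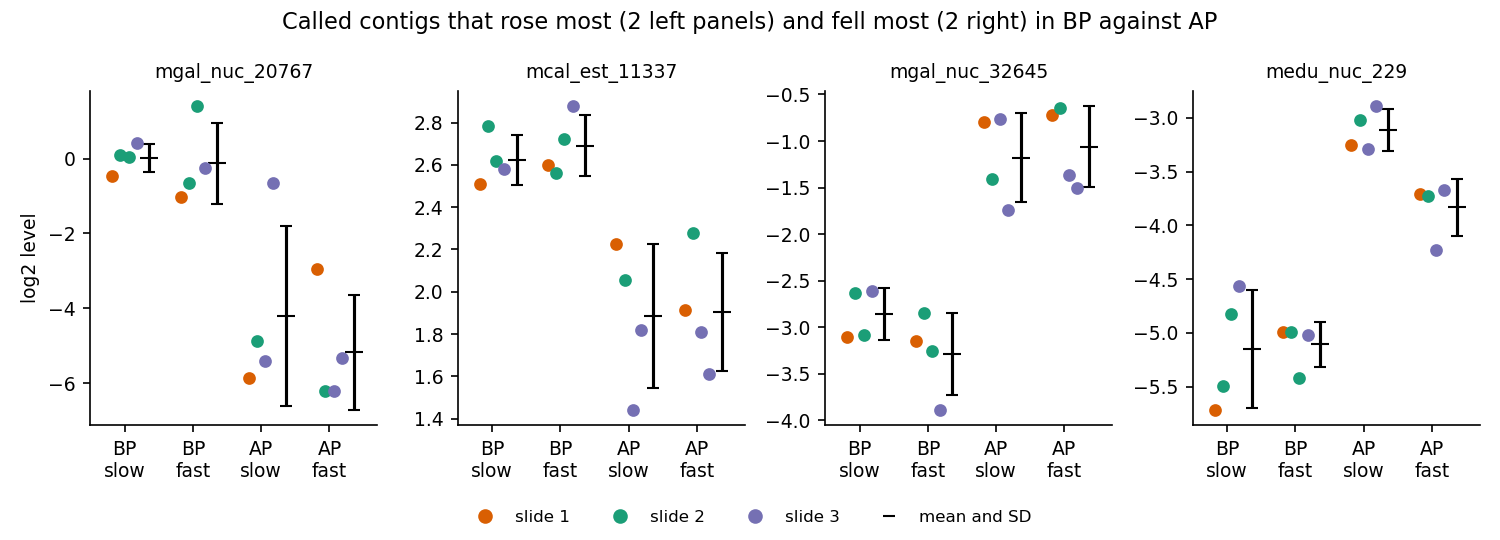
Level in each pool of the 2 called contigs that rose most and the 2 that fell most in BP against AP (log2 relative to the array's 75th percentile), by diet and growth class. Points are pools coloured by slide, and bars are the mean and SD of 4 pools. In mcal_est_11337 all 8 BP pools lie above all 8 AP pools, and in mgal_nuc_32645 and medu_nuc_229 all 8 lie below.

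All 9 diet calls kept their sign within each slide, but they were chosen from these same arrays. Diet, unlike growth class, was uneven over slides 2 and 3. With slide as a block 2 probes were called, both lower in BP, and mgal_nuc_20767 and mcal_est_11337 then had an adjusted p of 0.118, the highest over the alternatives of each. With normexp 3 probes were called and with quantile normalization 2, and in both settings all were lower in BP. The calls of mgal_nuc_20767 and mcal_est_11337 ended under 8 and 7 of their alternatives, that of medu_nuc_229 under 4 and that of mgal_nuc_32645 only without slide 1 (0.0648, range 0.00226 to 0.0648). With each pool left out in turn, mgal_nuc_20767 and mcal_est_11337 lost their calls in 14 of the 16 fits each, medu_nuc_229 in 3 and mgal_nuc_32645 in 0.

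Among slow growers limma called 0 probes between the diets (2705 with an unadjusted p under 0.05, smallest adjusted p 0.205). Among fast growers it called 1, mgal_nuc_32645, which was lower in BP, where its level fell by 2.23 log2 (SE 0.29, adjusted p = 0.0490, 2493 probes with an unadjusted p under 0.05). That call ended with slide as a block (adjusted p = 0.0505) and under 8 further alternatives, with an adjusted p of 0.0251 to 0.527 over all of them, and in 13 of the 16 fits with a pool left out. In slow growers the same contig differed by -1.68 log2, and the difference between the classes was not called (adjusted p = 1.00).

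Of the 60 named probes, 0 were called by limma between the diets. The 2 probes with the smallest p were of male-type mitochondrial names, COII_mgal_M (limma adjusted p = 0.257) and ATPase6_mgal_M (1.81 log2, SE 0.58, adjusted p = 0.311), both higher in BP. This COII_mgal_M probe was well above background in 3 of 4 pools of BP slow, 1 of 4 of BP fast and no AP pool, so its difference is given only as at least 1.39-fold. The other tested COII_mgal_M probes were at 1.27 log2 (adjusted p = 0.427) and 0.05 log2, and the other ATPase6_mgal_M probe at -0.13 log2 (adjusted p = 0.959). In slow growers 1 named probe, of COI_mgal_M, passed when adjusted over the named probes alone (2.63 log2, adjusted p over all probes 0.485), while the other COI_mgal_M probe was at -0.50 log2 (adjusted p = 0.977). In fast growers 0 passed either way. At the preset correlation the oxidative phosphorylation list gave camera p = 0.839 over both classes, 0.493 in slow growers and 0.685 in fast growers. The female-type names gave p = 0.514 and the male-type names p = 0.597 over both classes at the same correlation. With every probe of a list in place of 1 per name, 2 diet tests passed at the preset correlation. The oxidative phosphorylation list was lower in BP among slow growers (p = 0.0319 at this preset correlation), and the male-type names were higher in BP over both classes (p = 0.0349), although with 1 probe per name only 3 of the 9 were above 0, with a median of -0.13 log2, against 5 with normexp and with the authors' value table.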

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

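The fits with slide as a block, quantile normalization and an estimated correlation were planned as alternatives, but their use as tests of slide, of the scale of the arrays and of a shared source of variation, like the test of 1 other tissue, was chosen after the result was seen, while the tests of other splits, of male animals and of bright probes were set beforehand.

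Each slide holds as many fast as slow pools of each diet, so a slide difference that shifts all pools alike cancels in fast minus slow. Among the 250 probes called between fast and slow growers over both diets, 228 were still called with slide as a block. The block could change little but the spread, so this count does not test slides as a cause. With quantile normalization 199 of the 250 were still called, which argues against the scale of the arrays. Of 100 splits of the pools, only the real one called as many probes (250 against 135 in the highest other split, in which 1 fast and 1 slow pool of each diet had changed places), so such splits seldom reach this count. The growth class itself stays open as a biological explanation that was not tested apart from what goes with it, since the labels give no size, age or sex of the animals.

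In the called probes far lower in fast growers, 114 probes in 67 sequence groups, transcripts of another tissue or cell type in the slow pools could be the source. If 1 such source varied in share between pools, different sequence groups would vary together within groups of pools. The median correlation of deviations was 0.859 within the 19 sequence groups of more than 1 probe and 0.114 between the 67. The gap was 0.745 (95% interval 0.640 to 0.821, drawn over sequence groups and not over pools). The measured deviations of different sequence groups thus went largely apart. However, probes of 1 sequence group come from the same contig or from contigs that share sequence, and would correlate under any source. Noise in dim probes also lowers the correlation between groups, so the gap does not exclude 1 source. A varying share of male animals in the pools cannot be told apart from other sources. The mean deviation of the far lower probes, 1 per sequence group, was correlated with that of the male-type mitochondrial names across the 16 pools. This gave r = 0.0528 (permutation p = 0.844) and rho = -0.0824 (permutation p = 0.764), but the 95% interval of r, -0.537 to 0.608, is too wide to decide. Without the 2 pools farthest from the median r was -0.0621, and within slides 2 and 3 it was -0.257 and -0.452, with too few arrays on slide 1. Some male-type names were lowest on slide 1 in every group, so their deviations also hold a slide difference. Whether these names track the share of male animals in gill pools was not tested.

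The female-type mitochondrial names were higher in fast growers by a median of 0.13 log2, and part of this may come from array scale at the bright end. Probes of other names matched on level differed by a median of 0.04 log2, leaving 0.086 log2 between the medians, above 92.5% of random matched sets, which does not decide between scale and a change of these transcripts. At the preset correlation the call of camera was lost with quantile normalization (p = 0.50) and with the authors' value table (p = 0.407), which both set the distribution of every array equal, and the median fell from 0.13 to 0.04 and 0.03 log2. Slide as a block and normexp kept it. With the correlation among the probes estimated, camera gave p = 0.0748, consistent with 1 shared source of variation that moves all 12 names together from pool to pool. Growth class stays open as the biological explanation of the difference.

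Among 52 sets of 4 pools examined, 5 had a pool that stood apart from the others, where chance gives about 1 in 20 sets, or 2.6. In BP fast, pool 2 had a level of -2.45 log2 in mgal_nuc_12275, against -0.98 to -0.84 in the other pools. In medu_nuc_229, BP fast pool 3 was at -5.42 log2, against -5.02 to -4.99, with no pool of the group well above background. In the same contig AP fast pool 3 was at -4.23 log2, against -3.72 to -3.67. The mean of the female-type mitochondrial names was 8.44 log2 in AP fast pool 4, against 8.65 to 8.70 in the other AP fast pools. The share of spots well above background was 54.6% in AP fast pool 1, which lies on slide 1, against 68.7% to 69.8% in the other AP fast pools.

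The array design marks 534 spots as controls that carry contig names, and these were left out of every comparison. They gave signal above that of the negative controls on every array. The lowest share of them well above background on an array was 67.4%, while the negative controls gave 0% to 2.60%. Of the contigs called between fast and slow growers 9 have such a spot, and in 9 of 9 the spot had the sign of the call, with a correlation of 0.976 across these contigs, where 6 of the 9 spots carry the same sequence as a called probe. For the diets 1 called contig has such a spot, and it had the same sign.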

How the results depend on the processing

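The setting without the 4 arrays of slide 1, and the female-type and male-type lists, were chosen after seeing the data. No result changed direction past its threshold under any alternative. The growth count over both diets, 250, was 398 with array weights, 394 with pool number as a block, 549 at an adjusted p under 0.10, 143 with a change of at least 1 log2, 130 with 1 probe per name (fewer probes tested) and 83 without slide 1 (fewer samples). Under the other 10 alternatives it lay between 167 and 339, and with only probes well above background on all 16 arrays 120 were higher and 51 lower. Leaving out each pool gave 97 (AP slow pool 2) to 333 (BP slow pool 1). It was 120 and 121 without BP slow pool 3 and AP slow pool 4, 148, 129, 111 and 145 without BP fast pools 1 to 4, and 106 to 163 without AP fast pool 1, 2 or 4.

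The growth count in BP, 0, was 8 with normexp and without slide 1, 6 with the authors' value table, 2 with slide as a block and with array weights, and 12 at an adjusted p under 0.10, and 0 to 20 with a pool left out (20 without BP slow pool 4, 2 without BP slow pool 3, and 3 and 5 without BP fast pools 1 and 4). In AP it was 0 under all alternatives and 0 to 7 with a pool left out (7 without AP slow pool 3 or AP fast pool 3, 1 without AP slow pool 1). The diet count over both classes, 9, was 3 with normexp, without a filter and without a trend, 2 with quantile normalization and with slide as a block, 5 with only probes well above background on all 16 arrays, 27 with array weights, and 4 with a change of at least 1 log2 and without slide 1. It was 2 (AP slow pool 3) to 11 (BP slow pool 1) with a pool left out, and 4 or fewer in 12 of the 16 fits. In slow growers the diet count, 0, was 1 without a trend, and 0 to 1 with a pool left out (1 without BP slow pool 1). In fast growers the count, 1, was 0 with normexp, quantile normalization, the authors' value table, no filter, the strict filter, slide as a block, no trend and only the 8 arrays compared, and 2 with array weights, and it was 0 to 9 with a pool left out, 9 without AP fast pool 3, 2 without AP slow pool 4 or AP fast pool 4 and 0 in 12 fits. The difference of growth differences stayed at 0, and was 0 to 4 with a pool left out (4 without AP fast pool 3, 1 without BP fast pool 1). The correlation between the diets' growth differences, 0.279, was 0.368 with the strict filter and 0.228 to 0.310 with a pool left out.

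The oxidative phosphorylation list in the growth comparison lost its call with quantile normalization (p = 0.657), the authors' value table (p = 0.506) and an estimated correlation (p = 0.0531), and gave 6.79e-05 to 0.00315 with a pool left out. Its calls in BP and in AP alone, and that of the female-type names, were lost under the same 3 alternatives. In AP alone its call at the preset correlation (p = 0.0187) was also lost without AP slow pool 1 (0.102), AP fast pool 3 (0.0942) or slide 1 (0.0869). In the diet comparison it gave 0.454 to 0.954 with a pool left out. With every probe of a list, 2 diet calls were gained at the preset correlation (p = 0.0319 and 0.0349). The cause of these changes was not tested except where stated.

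The labels link no pools by number, which is taken as a name only. Of 24 pairs with the same number in different groups, 7 deviated together with a correlation over 0.1 (range -0.0466 to 0.263), among them all 6 pairs of pool 1, whose 4 arrays all lie on slide 1, so that number and slide cannot be told apart there. The mean was 0.0838 for the same number and -0.0275 for other numbers, and 8 of the 16 arrays correlated best with their own number. With pool number as a block the diet count was also 3 and that in fast growers 0, and a probe of ND4L_mgal_F gained a growth call (adjusted p = 0.0496, range 0.0426 to 0.223). Except for the growth count, no other count over all probes and no list changed its call.

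Low signal limits the falls most, since 47 of the 128 lower probes were well above background on all 16 arrays. For single contigs and probes, 339 values kept their side of the threshold under the alternatives, 34 lost a call and 4 gained 1.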

Other observations

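The tests of cysteine-rich probes were chosen after the result was seen, while the splits of the pools were set beforehand.

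For 7776 contigs, probes of both of the array's single-probe sets were tested. In 468 of them the pair overlaps as reverse complements, and in 0 on the same strand, so that the sets read opposite strands there. Fast minus slow differences of the pairs correlated at 0.534 across contigs, which are not independent replicates. Of the 79 contigs with a called probe in either set, 69 had the same sign in both, with a correlation of 0.826, and in 9 both probes were called.

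Of the 9 male-type mitochondrial names tested, 4 were lowest on slide 1 in every group. On slide 1, relative to slides 2 and 3, COII_mgal_M differed by a mean of -2.72 log2, ATPase6_mgal_M by -2.12, ND5_mgal_M by -1.28 and ND3_mgal_M by -1.19. The other 5 went less far, with ND6_mgal_M at -1.11 log2 and CYTB_mgal_M at -0.86 (slide 1 lowest in 3 of 4 groups), COI_mgal_M at -0.86 (2 of 4), COIII_mgal_M at -0.21 and ND2_mgal_M at 0.01 (1 of 4 each). The names were picked out after their values were seen, and no test of the slides was run on them. Over all tested probes the median was -0.01 log2, and the female-type names ranged from -0.07 to 0.13.

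Mussels make many cysteine-rich defence peptides, and a hypothesis was that such transcripts are frequent among the contigs that differed with growth. A probe was counted if a reading frame held 4 or more cysteines. Among sequence groups lower in fast growers 3 of 79 (3.80%) did, against 508 of 20685 other tested contigs (2.46%), and Fisher's exact test (one-sided) gave p = 0.308 (adjusted 0.616), too few to decide. Among sequence groups higher in fast growers 1 of 76 (1.32%) did, with p = 0.849 in the same exact test (adjusted 0.849), also too few to decide.

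Other splits of the pools were set beside each result. For the diet count over both classes, only the real one of 100 splits gave as many as 9, with 1 in the highest other split, so such splits seldom reach this count. The splits moved pools across slides, over which diet is uneven, and most of the 9 calls were lost with slide as a block. For the correlation of the growth differences between diets, only the real one of 100 relabellings of fast and slow gave as much as 0.279. Relabelling seldom reaches this value, although the highest other, 0.276, was close. For the oxidative phosphorylation list 3 of 100 splits, the real one among them, gave a camera p as small as 0.000653 in the growth comparison. The smallest of the others was 0.000348. This count does not exclude chance, since 27 of the other splits gave a camera p under 0.05 at the preset correlation. The list's call was also lost with an estimated correlation (camera p = 0.0531) and with quantile normalization (p = 0.657). Chance cannot be excluded for the single diet call in fast growers (4 of 35 splits gave as many as 1, highest other 1), nor for the list between diets (camera at the preset correlation gave p = 0.839, 87 of 100 splits gave as little or less, and the smallest other was 0.000511). For counts of 0 every split gives as many: 35 of 35 in BP, in AP and for the diets in slow growers, with 2 in the highest other split of each, and 100 of 100 for the difference of growth differences, also with 2.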
